A study of Homo sapiens with 16 samples.

How the data were processed

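Total RNA of 2 human carcinoma cell lines was hybridised to 16 one-colour expression arrays per the labels, on 2 slides of 8 arrays per the barcodes in the file headers. The 8 groups were HCT116 and MCF7, each as control or after 48 h with the butanol, chloroform or ethanol fraction of Micromeria fruticosa, with 2 arrays per group. The dose is 100 µg per ml per the labels, while the treatment protocol gives it per microlitre, and this conflict could not be settled from the files. The labels state neither the vehicle nor whether replicates were separate cultures.

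The processed signal of each spot is an intensity that, per the file headers, Agilent Feature Extraction 11.5.1.1 made by subtracting background and detrending within the array, with a small surrogate value for spots not above background. The mean spot and local background signals are also intensities in scanner units, as deposited and not normalised between arrays. The submitters' table of values holds log2 processed signals which the authors averaged per gene name and shifted per array so that the 75th percentile lies near 0. Tests on the files gave this description of the table, which had 9 missing values. The other columns used, as deposited, are quality flags of 0 or 1 per spot, including the flag for a signal well above background. Probe coordinates are on hg19 per the file headers. Each array had 60901 spots, of which 2075 were controls, and 58201 distinct probes with 43317 gene names. Of the probes, 31100 were matched to a gene by accession, 3369 by symbol and 497 by synonym, and 23235 had no match. Exon and UTR positions were not analysed here.

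Processed signals were taken to log2 and the 75th percentile of each array was subtracted. Each gene name was represented by its brightest probe on average, and genes well above background on both arrays of at least 1 of the 8 groups were kept, which gave 25406 genes. Between 43.1% and 54.3% of the probes were well above background per array, and no spot was saturated. A linear model with 8 group means was fitted to all arrays with limma 3.58.1 in R 4.3.3, with moderated variances (8 residual and 4.32 prior degrees of freedom). Benjamini-Hochberg adjustment was made within each comparison over all genes, and an adjusted p under 0.05 is called a rise or fall. Tests were two-sided. The 16 comparisons were each fraction against control in each line, the 3 pairs of fractions in each line, the difference of each fraction's effect between the lines, and the control arrays of MCF7 against those of HCT116. Groups of 2 arrays allow no exact test below 0.05 and no count of other splits. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

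The comparisons, the 31 gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. The lists cover cell cycle (G1/S and replication, G2/M and mitosis), p53 targets, pro-apoptotic and anti-apoptotic genes, NRF2 targets, integrated stress, unfolded protein response, heat shock, metallothionein and zinc, AHR targets, xenobiotic metabolism, cholesterol and fatty acid synthesis, hypoxia and glycolysis, oxidative phosphorylation, ribosome biogenesis, autophagy and lysosome. They further cover NF-kB and inflammation, interferon response, immediate early and MAPK genes, oestrogen response, WNT targets, mesenchymal and epithelial genes, markers of each line, housekeeping genes, and leukocyte, fibroblast and endothelial markers. The 29 lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, adjusted over 174 tests for the comparisons with control, and again with an estimated correlation. Camera compares a list with all other genes. Members are also reported adjusted over the list alone. The 36 listed G1/S genes gave 37 gene names.

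Named genes were, for each fraction against control, the 5 higher and 5 lower genes with the largest change among those that passed, had a gene symbol and had both treated arrays on the same side of both control arrays. To these came up to 3 members with the smallest adjusted p of each list that passed, up to 20 such genes in order of the list's p. Pairs of fractions and differences between lines gave 3 and 3 genes, and the control arrays gave the line markers. Other genes were chosen after their values were seen. "At least" folds raise the lower group to the lowest level well above background on each array.

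The alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' log2 table, no filter on dim genes, genes well above background on all arrays (14827), every probe apart (32892), a minimum change of 2-fold, camera with an estimated correlation, only the arrays of the line, a block for the replicate numbers in the HCT116 titles, and each array left out in turn. After the data were seen, these were added: leaving out the 3 dimmest arrays (HCT116 chloroform 2, MCF7 chloroform 1 and MCF7 ethanol 1), fitting only the groups compared, and leaving out probes with a run of 7 or more alternating G and A bases (25111 genes left).

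The pipeline was tested on simulated data, made from the mean levels of each line and the spread of each group, with known changes added. At a log2 change of 1 it recovered between 0% and 2.99% of the changed genes over the 6 comparisons with control, at 2 between 13.4% and 25.4%, and at 3 between 65.2% and 83.3%, with at most 9 false calls among 25134 unchanged genes. Changes of 2-fold were thus mostly missed here, which need not hold where many genes changed.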

Results

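Transcript levels were measured with 16 one-colour microarrays in HCT116, a human colorectal carcinoma line, and MCF7, an oestrogen receptor positive human breast carcinoma line. Cells of each line were kept for 48 h as controls or with the butanol, chloroform or ethanol fraction of Micromeria fruticosa, a plant of the mint family. Each of the 8 groups held 2 arrays, so n = 2 stands behind every group mean below. The sample labels give the dose as 100 µg per ml, whereas the treatment protocol gives the same figure per microlitre, and no vehicle for the controls is stated. The 75th percentile of the processed signal lay between 112 and 174 on the 4 control arrays and between 125 and 171 on the 4 butanol arrays. In HCT116 it was 102 and 58.9 with chloroform and 92.4 and 103 with ethanol. In MCF7 it was 55.3 and 76.7 with chloroform and 46.8 and 76.5 with ethanol. All HCT116 arrays were on 1 slide and all MCF7 arrays on the other. Replicate arrays correlated across genes with r between 0.925 (HCT116 chloroform) and 0.988 (HCT116 control), where genes are not independent replicates.

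**Figure D1:**
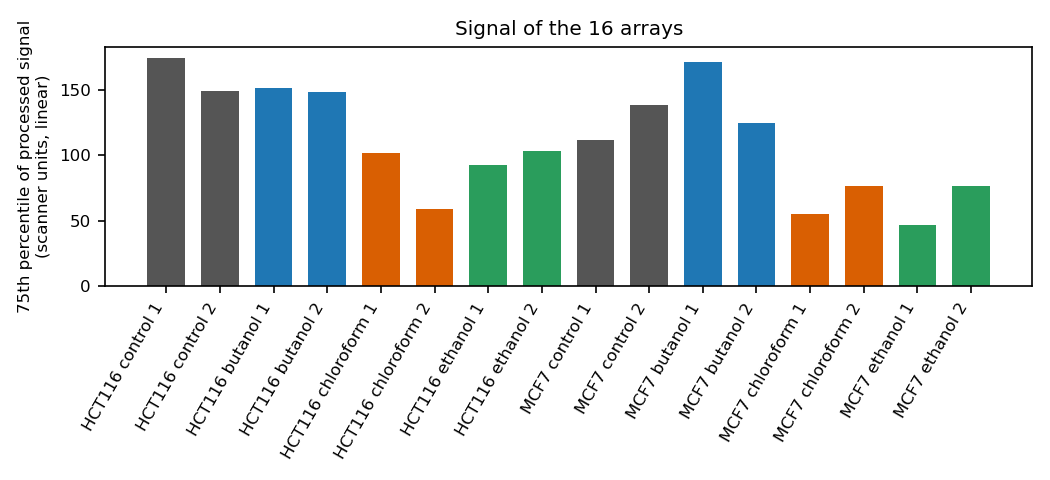
75th percentile of the processed signal (linear scanner units) of each of the 16 arrays, coloured by group (grey control, blue butanol, orange chloroform, green ethanol). The lowest bars are MCF7 ethanol 1 at 46.8, MCF7 chloroform 1 at 55.3 and HCT116 chloroform 2 at 58.9.

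Levels are log2 signals relative to the 75th percentile of the array, given as mean ± SD. Changes are log2 differences ± SE from limma with its adjusted p, and each SE rests on the spread pooled over the 8 groups. That pooled spread was generous to chloroform, whose own replicates spread 1.45 (HCT116) and 1.18 (MCF7) times as far, and to MCF7 ethanol, at 1.17 times, and strict for butanol, at 0.711 and 0.835 times. The p-values measure only the spread between these arrays, which may be technical, since the labels do not say whether the replicates were separate cultures. Where leaving out 1 array ended a list's call, the array giving the highest p is named with that p. "At least" folds are for genes not above background in the lower group and were taken against the lowest level that counted as above background. List medians are over all measured members of a list. The title of the series names antitumour activity of the plant on cancer cell lines. The comparisons with control ask what each fraction did to the transcripts of each line, those between fractions whether the fractions differed, and the interactions whether the lines responded differently.

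In HCT116 with the butanol fraction, 1 gene changed. GGT5, a gamma-glutamyltransferase acting on glutathione conjugates, fell from -1.16 ± 0.28 to -4.88 ± 0.74, a change of -3.72 ± 0.43 (adjusted p = 0.034), at least 6.7-fold lower. Its probe lies on chromosome 22 at 24615623 to 24615682 of hg19, the assembly of the probe coordinates. In the list of NRF2 targets, the genes of the oxidative stress response, 25 of 26 members were higher, with a median change of 0.55 (camera adjusted p = 3.81e-09, but adjusted p = 0.136 with an estimated correlation). None of them passed over all genes and 2 did adjusted over the list alone, among them HMOX1, the haem oxygenase gene, at 6.34 ± 0.12 against 4.71 ± 0.32. The 25 ribosome biogenesis genes were all lower, with a median of -0.35 (adjusted p = 2.85e-06, and adjusted p = 0.274 with an estimated correlation). Targets of the aryl hydrocarbon receptor (AHR), a sensor of planar xenobiotics, were higher for 8 of 10, with a median of 0.75 (adjusted p = 0.00133, and adjusted p = 0.42 with an estimated correlation). CYP1A1, the classical AHR target, was at 2.40 ± 0.06 against 0.29 ± 0.03, a change of 2.11 ± 1.36 that did not pass.

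The other HCT116 list shifts with butanol were small, and the call of each was lost with 1 array left out. Autophagy and lysosome genes had a median of 0.36 (adjusted p = 0.000453, 0.0534 without control 1, and adjusted p = 0.42 with an estimated correlation). The integrated stress list had -0.39 (adjusted p = 0.00205, 0.117 without butanol 1, and adjusted p = 0.671 with an estimated correlation). Interferon response genes had 0.31 (adjusted p = 0.00858, 0.163 without butanol 2, and adjusted p = 0.556 with an estimated correlation). The immediate early and MAPK list had -0.21 (adjusted p = 0.0328, 0.729 without control 2, and adjusted p = 0.556 with an estimated correlation). The xenobiotic metabolism list had 0.19 (adjusted p = 0.0497, 0.537 without control 1, 0.0578 under quantile normalization, and adjusted p = 0.397 with an estimated correlation). No member of the ribosome biogenesis, AHR or these lists passed over all genes or adjusted over the list alone. The limma test made its 1 call among 25406 genes, with 618 at an unadjusted p under 0.05. GGT5 had adjusted p = 0.089 without the 3 dimmest arrays, 13 of the 16 arrays left out in turn gave 0 genes, and leaving out butanol 1 gave 23.

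In HCT116 with the chloroform fraction, 3257 genes rose and 1657 fell. DKK1, a secreted WNT inhibitor that is itself a WNT target, fell from 7.04 ± 0.18 to 0.67 ± 0.58, a change of -6.37 ± 0.96 (adjusted p = 0.0026), 82.5-fold. UBASH3B, a tyrosine phosphatase, fell by 5.13 ± 0.36 (adjusted p = 6.4e-05) and PDE4B, a cAMP phosphodiesterase, by 4.63 ± 0.49 (adjusted p = 0.00048). SOX4, a developmental transcription factor, changed by -4.69 ± 0.85 (adjusted p = 0.0054), and SERPINA5, a serine protease inhibitor, by -4.82 ± 0.64 (adjusted p = 0.0015), at least 7.26-fold lower. Of the 5 largest rises, IFNA22P, an interferon alpha pseudogene, went from -5.27 ± 0.25 to 2.44 ± 0.86 (7.71 ± 1.07, adjusted p = 0.0019, at least 95.3-fold). C6orf222 changed by 7.67 ± 1.19 (adjusted p = 0.003, at least 68.3-fold). The other probes in that group, for LRRC2 (7.72 ± 1.96, at least 147-fold), BICC1 (7.43 ± 2.01, at least 35.7-fold) and CD86 (7.29 ± 1.89, 157-fold), carry runs of 11, 9 and 12 alternating G and A bases. Their SDs between the chloroform arrays were 5.58, 5.67 and 5.45. With such probes passed over, a step chosen after the values were seen, the next were KIF25-AS1 (7.04 ± 0.68, at least 27.8-fold), IFNA8 (6.42 ± 0.67, at least 18.1-fold) and KCTD4 (6 ± 0.84, at least 14.5-fold).

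WNT target genes moved both ways in HCT116 with chloroform. Of 19, 9 fell, 2 rose and 8 did not pass, and adjusted over the list alone 10 fell and 3 rose. RNF43, a ubiquitin ligase that limits WNT receptors, fell by 3.67 ± 0.33 (adjusted p = 0.00024). The growth factor BMP4 (-4.22 ± 0.60), AXIN2 (-2.42 ± 0.63), SP5 (-2.66 ± 0.57) and MYC (-2.31 ± 0.67) also fell, whereas TNFRSF19 (3.62 ± 0.90) and ASCL2 (2.97 ± 0.77) rose. The median of the list was -1.31 (camera adjusted p = 0.00033, and adjusted p = 0.316 with an estimated correlation). All 35 G2/M and mitosis genes were lower, with a median of -1.19 (adjusted p = 8.16e-08, and adjusted p = 0.608 with an estimated correlation), and 7 of them fell, over all genes as well as adjusted over the list alone. Among these were the spindle motor KIF11 (-3.27 ± 0.68), the centromeric histone CENPA (-3.38 ± 0.72) and the checkpoint kinase TTK (-2.38 ± 0.51). Without the 3 dimmest arrays, which left chloroform 1 alone, the median of this list was -1.92. On chloroform 2 it was -0.69. In the G1/S and replication list, 7 of 37 fell and 1 rose, 10 and 1 adjusted over the list alone, with a median of -0.94 (adjusted p = 1.08e-06, and adjusted p = 0.507 with an estimated correlation). Its members E2F2, a cell cycle transcription factor (-2.46 ± 0.55), POLE2, a polymerase subunit (-2.73 ± 0.65), and GINS3 of the replicative helicase (-1.78 ± 0.39) fell, and C2orf48 (1.29) rose. This became 13 and 0 without the 3 dimmest arrays.

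Metal and cholesterol genes also moved in HCT116 with chloroform. SLC30A1, a zinc exporter induced by zinc, rose by 2.64 ± 0.46 (adjusted p = 0.0046) and MT1L of the metallothionein family by 2.03 ± 0.53, while the zinc importer SLC39A10 fell by 2.18 ± 0.59. Of the 11 metallothionein and zinc genes 4 rose and 1 fell, 7 and 1 adjusted over the list alone, with a median of 1.43 (adjusted p = 0.0268, 0.123 without chloroform 1, 0.0927 with normexp, and adjusted p = 0.546 with an estimated correlation). HMGCR, the rate-limiting enzyme of cholesterol synthesis, fell by 2.47 ± 0.54, and DHCR24 (-2.30 ± 0.53) and PCSK9 (-2.43 ± 0.62) fell too. Of 25 cholesterol genes 5 fell and MSMO1 (1.40) rose, the same counts adjusted over the list alone. Their median was -0.25 (adjusted p = 0.0129, 0.26 under quantile normalization, and adjusted p = 0.665 with an estimated correlation). Of 27 hypoxia and glycolysis genes 2 fell, 1 adjusted over the list alone, namely EGLN3 (-3.73 ± 0.76, at least 3.16-fold lower) and PFKFB4 (-1.47 ± 0.46). Their median was -0.58 (adjusted p = 0.000399, and adjusted p = 0.42 with an estimated correlation). Of 25 ribosome biogenesis genes 5 fell, also adjusted over the list alone, including WDR43 (-1.59 ± 0.33), the RNA polymerase I subunit POLR1B (-1.71 ± 0.37) and TWISTNB (-1.53 ± 0.35). Their median was -0.58 (adjusted p = 0.00089, and adjusted p = 0.42 with an estimated correlation).

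The remaining HCT116 chloroform calls were weaker. In the unfolded protein response list DNAJC3 rose by 2.01 ± 0.38, DNAJB9 by 2.53 ± 0.74 and DNAJB11 by 1.15, 3 of 20 over all genes and adjusted over the list alone. Their median was 0.56 (adjusted p = 0.0362, 0.754 without chloroform 1, 0.345 with normexp, and adjusted p = 0.608 with an estimated correlation). Of 24 pro-apoptotic genes CASP2 (-1.85) and FADD (-2.15) fell and BNIP3L (3.01) rose, 1 and 1 adjusted over the list alone. Their median was -0.51 (adjusted p = 0.0474, 0.245 without chloroform 2, 0.228 without the 3 dimmest arrays, 0.48 under quantile normalization, and adjusted p = 0.507 with an estimated correlation). No oxidative phosphorylation gene passed either adjustment. Their median was -0.29 (adjusted p = 0.025, 0.487 without chloroform 1, and adjusted p = 0.851 with an estimated correlation). Lists that missed the threshold still held genes that rose, such as HMOX1 by 3.77 ± 0.45 (adjusted p = 0.00087) and the DNA damage response gene GADD45A by 2.65 ± 0.53. The heat shock gene HSPA1A (4.44 ± 0.87) and the immediate early genes FOS (4.13 ± 1.13) and EGR1 (2.64 ± 0.77) rose as well. Of 27 immediate early genes 5 rose and 3 fell, 7 and 4 adjusted over the list alone and 1 and 1 without the 3 dimmest arrays, with a median of 0.77 beside a camera direction of down (adjusted p = 0.985). NRF2 targets had 5 of 26 that rose (median 0.34, adjusted p = 0.477) and p53 targets 5 of 29 (median 0.36, adjusted p = 0.266), the same counts adjusted over the list alone. The p53 list passed under quantile normalization (median 0.55, adjusted p = 0.00877). Its median was 0.74 without the 3 dimmest arrays, which left chloroform 1 alone.

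Many HCT116 chloroform rises were dim or lacked a protein coding annotation. Of the 3257 that rose, 30.2% had one, against 92.5% of the fallers and 59.3% of all tested, and 1112 were not above background on either control array. Leukocyte marker genes, which carcinoma cells mostly lack, had a median of 1.58 (adjusted p = 0.221). Of 8, 3 rose, including CD14 (2.53 ± 0.53), and HLA-DRA (-2.35 ± 0.61) fell, 5 and 1 adjusted over the list alone. Among fibroblast and endothelial markers, too few for a test, FAP (3.12), THY1 (4.40) and EMCN (2.12) rose and COL1A1 (-2.66) fell, and none passed in the other comparisons with control. The median change of all genes was 0.22 with percentile scaling and -0.04 with quantile normalization, under which 1254 genes were higher and 1487 lower. The limma count of 4914 was 1209 without control 1, 800 without control 2, 1990 without chloroform 2 and 144 with only the groups compared, while 2340 rose and 1971 fell without the 3 dimmest arrays.

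In HCT116 with the ethanol fraction, cell cycle genes were lower as a set, and 166 genes rose and 172 fell. All 37 names of the G1/S and replication list were lower, with a median of -1.99 (camera adjusted p = 8.15e-31, and adjusted p = 0.14 with an estimated correlation). Of these 13 fell over all genes and 36 adjusted over the list alone, with GINS2 of the replicative helicase changing by -2.69 ± 0.39 (adjusted p = 0.01), the transcription factor E2F1 by -2.40 ± 0.36 (adjusted p = 0.012) and the replication factor MCM10 by -2.34 ± 0.42 (adjusted p = 0.023). All 35 G2/M and mitosis genes were lower with a median of -2.01 (adjusted p = 5.05e-19, and adjusted p = 0.442 with an estimated correlation), none over all genes and 33 adjusted over the list alone. Examples are TTK at 0.44 ± 0.40 against 2.46 ± 0.18 and CDK1 at 3.43 ± 0.56 against 5.30 ± 0.23. Over all genes 31 of the G1/S and 30 of the G2/M genes fell without the 3 dimmest arrays. MMP7, a matrix metalloproteinase, fell from 0.22 ± 0.29 to -5.51 ± 0.16 (-5.72 ± 0.45, adjusted p = 0.00051, at least 11.9-fold lower), and the imprinted non-coding RNA H19 changed by -4.76 ± 0.69 (at least 5.61-fold lower). The neuronal genes CNTNAP2 (-4.01 ± 0.59, at least 3.89-fold lower), VSNL1 (-3.96 ± 0.59, 15.5-fold) and NCAM1 (-3.93 ± 0.58, at least 3.54-fold lower) also fell. The organic anion transporter SLCO2B1 rose from -6.37 ± 0.12 to 0.07 ± 0.57 (6.44 ± 0.57, adjusted p = 0.00098, at least 18.5-fold). Other large rises were SPANXA1 (5.31 ± 0.91, at least 13.4-fold), the thrombin receptor gene F2RL2 (5.18 ± 0.76, at least 21.1-fold), the phospholipase PLA2G4C (4.36 ± 0.61, 20.5-fold) and the hair keratin KRT34 (4.23 ± 0.51, at least 16.8-fold).

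Oxidative stress and NF-kB genes were higher in HCT116 with ethanol. SQSTM1, an autophagy adaptor and NRF2 target, rose by 3.45 ± 0.55 (adjusted p = 0.014), HMOX1 by 2.67 ± 0.45 and the ferritin light chain FTL by 1.85 ± 0.32. Of 26 NRF2 targets 4 rose, 12 adjusted over the list alone. Their median was 1.21 (adjusted p = 3.63e-09, and adjusted p = 0.136 with an estimated correlation). NFKB2 rose by 2.39 ± 0.50 and RELB, its partner, by 2.61 ± 0.54, 2 of 22 NF-kB and inflammation genes and 9 adjusted over the list alone. Their median was 1.33 (adjusted p = 1.64e-05, and adjusted p = 0.397 with an estimated correlation). The sterol enzymes MSMO1 and IDI1 rose by 1.96 ± 0.37 and 2.05 ± 0.43, 2 of 25 cholesterol genes and 7 adjusted over the list alone. Their median was 0.69 (adjusted p = 0.000236, 0.29 with normexp, and adjusted p = 0.546 with an estimated correlation). SQSTM1 and MAP1LC3B, which marks autophagosomes and rose by 2.09 ± 0.46, were the 2 of 28 autophagy and lysosome genes, 7 adjusted over the list alone. Their median was 0.52 (adjusted p = 0.000432, 0.426 with normexp, and adjusted p = 0.42 with an estimated correlation). Metallothionein and zinc genes had a median of 1.12 with none over all genes, and 6 higher and 1 lower adjusted over the list alone, such as MT1X at 5.12 ± 0.37 against 3.05 ± 0.40 (adjusted p = 0.00306, 0.0978 with normexp, and adjusted p = 0.47 with an estimated correlation). Ribosome biogenesis had a median of -1.04, none over all genes and 10 lower over the list alone (adjusted p = 6.01e-10, and 0.136 with an estimated correlation). Without the 3 dimmest arrays, at the same medians, 11 NRF2, 7 NF-kB, 7 cholesterol and 6 autophagy genes rose and 4 ribosome biogenesis ones fell.

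Further HCT116 lists also passed with ethanol. Targets of p53 had a median of 0.52, with none over all genes and 2 adjusted over the list alone (adjusted p = 0.00176, 0.368 with normexp, and adjusted p = 0.507 with an estimated correlation). Oxidative phosphorylation had -0.60 with none in either count (adjusted p = 7.45e-06, and adjusted p = 0.643 with an estimated correlation). Integrated stress genes had 0.58 with 1, ATF3, adjusted over the list alone (adjusted p = 0.0328, 0.613 without control 1, 0.0718 without the 3 dimmest arrays, 0.859 with normexp, and adjusted p = 0.79 with an estimated correlation). Heat shock genes had -0.32 with 2 lower adjusted over the list alone (adjusted p = 0.0369, 0.106 without ethanol 1, 0.055 without the 3 dimmest arrays, and adjusted p = 0.507 with an estimated correlation). WNT targets had -0.59, where RNF43 fell by 2.11 ± 0.33 and 2 fell and 1 rose adjusted over the list alone (adjusted p = 0.0392, 0.337 without ethanol 1, 0.0511 under quantile normalization, and adjusted p = 0.507 with an estimated correlation). The limma test gave 338 genes, with 3 without control 1, 16 without control 2, 73 without ethanol 1, 23 without ethanol 2, 159 without either butanol array, 180 without either MCF7 butanol array, and 795 without either chloroform array. It was 43 with only the HCT116 arrays, 0 with a block for the title numbers and 1390 with only the groups compared. The split was 526 higher and 1461 lower with normexp, whose median over all genes was 0.22 against 0.08 here, and 872 higher and 1066 lower without the 3 dimmest arrays.

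**Figure D2:**
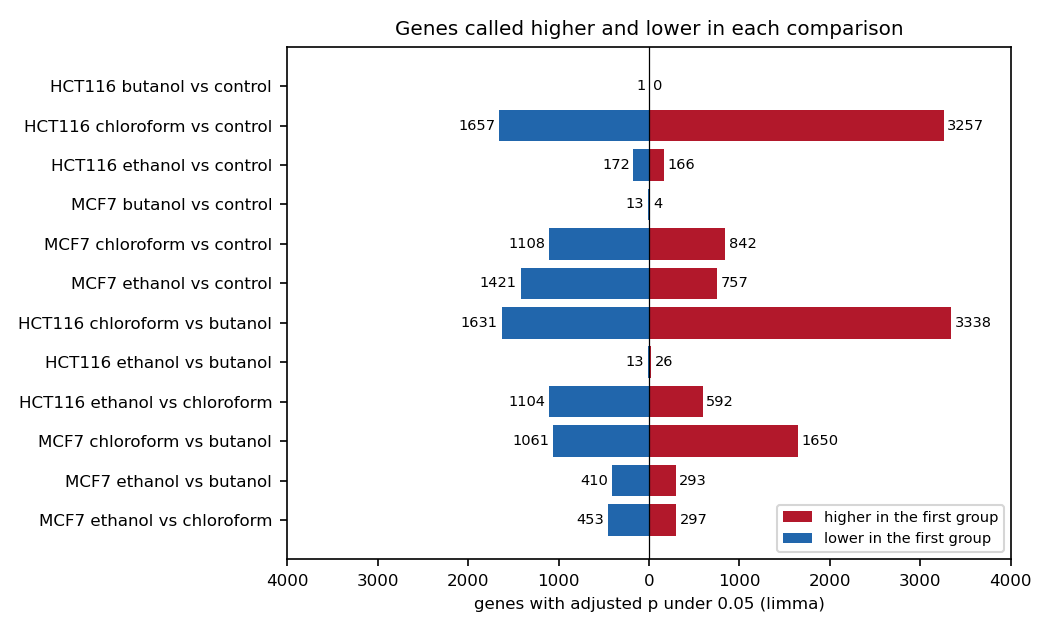
Number of genes called higher (red) or lower (blue) in the first named group of each comparison, limma adjusted p under 0.05, 2 arrays per group. Butanol against control has 1 gene in HCT116 and 17 in MCF7, and chloroform against control in HCT116 has 3257 higher and 1657 lower.

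In MCF7 with the butanol fraction, interferon response and NRF2 target genes were higher as sets, while 4 genes rose and 13 fell. Of 31 interferon response genes 28 were higher with a median of 1.23 (camera adjusted p = 1.77e-15, and adjusted p = 0.136 with an estimated correlation), none over all genes and 9 adjusted over the list alone. STAT1, the transcription factor of interferon signalling, stood at 4.46 ± 0.38 against 2.64 ± 0.10, the antiviral IFIT1 at 6.24 ± 0.21 against 4.36 ± 0.06 and OAS3 at 1.30 ± 0.50 against -0.60 ± 0.46. Of 26 NRF2 targets 24 were higher with a median of 1.34, none over all genes and 5 adjusted over the list alone, with HMOX1 at 7.54 ± 0.28 against 5.33 ± 0.31 (adjusted p = 8.02e-13, and adjusted p = 0.136 with an estimated correlation). All 10 AHR targets were higher with a median of 0.62 and none in either count, and CYP1A1 stood at 3.42 ± 0.20 against -0.86 ± 1.88 (adjusted p = 0.000515, and adjusted p = 0.413 with an estimated correlation). Of 29 oestrogen response genes 26 were lower with a median of -0.81 (adjusted p = 1.8e-07, and adjusted p = 0.397 with an estimated correlation), and AGR3 fell by 3.37 ± 0.50 (adjusted p = 0.037, at least 2.58-fold lower), 1 gene in either count.

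Single genes that passed in MCF7 with butanol included BANK1, a B cell adaptor gene, which fell from 0.23 ± 0.40 to -3.54 ± 0.01 (-3.77 ± 0.49, adjusted p = 0.022, 13.6-fold). CLEC3A, a cartilage lectin, changed by -5.01 ± 0.75 (at least 10.5-fold lower), the pseudogene A2MP1 by -4.90 ± 0.68 (at least 6.63-fold lower) and the germ cell gene ASZ1 by -3.48 ± 0.54 (at least 3.5-fold lower). MAPRE2, a microtubule end-binding protein, was the named gene that rose, by 2.53 ± 0.36 (adjusted p = 0.03, 5.79-fold). Other list shifts were autophagy and lysosome at 0.46 (adjusted p = 6.27e-05, and adjusted p = 0.397 with an estimated correlation) and MCF7 line markers at -0.75 with 1 lower adjusted over the list alone (adjusted p = 0.00131, a call lost without butanol 2, and adjusted p = 0.507 with an estimated correlation). Ribosome biogenesis genes had -0.38 (adjusted p = 0.00678, 0.184 without butanol 1, 0.184 with normexp, and adjusted p = 0.501 with an estimated correlation). NF-kB genes had 0.45 (adjusted p = 0.00684, 0.223 without control 2, and adjusted p = 0.524 with an estimated correlation) and xenobiotic metabolism genes 0.59 (adjusted p = 0.0268, 0.132 without control 1, and adjusted p = 0.325 with an estimated correlation). Immediate early genes had 0.49 (adjusted p = 0.0392, 0.951 without control 2, 0.0823 under quantile normalization, 0.122 with normexp, and adjusted p = 0.584 with an estimated correlation) and WNT targets -0.24 (adjusted p = 0.0474, 0.32 without control 1, 0.0533 under quantile normalization, 0.104 with normexp, and adjusted p = 0.507 with an estimated correlation). Other members of these 7 lists did not pass in either count. The limma test made 17 calls, with 1462 at an unadjusted p under 0.05. It made 0 without either control array or butanol 1, 1 without butanol 2, 5 without either HCT116 control or butanol array, 9 without either HCT116 ethanol array, and 26 without either HCT116 chloroform array. The split was 28 higher and 43 lower without the 3 dimmest arrays, 5 and 5 with quantile normalization and 1 and 8 with normexp, under which the median of all genes was -0.11 against -0.07 here.

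In MCF7 with chloroform, metallothionein and zinc genes were higher and interferon, cell cycle and oestrogen response genes lower as sets. The fall of the cell cycle genes rested mainly on chloroform 1. The zinc exporter SLC30A1 rose from 1.52 ± 0.10 to 5.62 ± 0.23 (4.10 ± 0.46, adjusted p = 0.0021, 17.1-fold), and the metal-binding MT1X by 3.55 ± 0.68. MT1F rose by 3.73 ± 0.55 on a probe with a run of 7 alternating G and A bases. Of 11 members 8 rose, 9 rose and 1 fell adjusted over the list alone, and the median was 2.47 (camera adjusted p = 4.8e-06, and adjusted p = 0.316 with an estimated correlation). In the fit without the 3 dimmest arrays 4 rose and the median was 2.01. Of 31 interferon response genes 27 were lower and 3 fell, 10 adjusted over the list alone, with IFIT1 at -2.79 ± 0.59 (adjusted p = 0.019), IFIT5 at -2.78 ± 0.57 and OAS2 at -2.49 ± 0.57. Their median was -1.03 (adjusted p = 5.65e-06, and adjusted p = 0.397 with an estimated correlation), and 5 fell without the 3 dimmest arrays. ZNF91, a zinc finger repressor of retroelements, fell by 5.07 ± 0.56 (adjusted p = 0.0021, 33.6-fold). The PI3K regulatory subunit PIK3R1 (-4.75 ± 0.85), SCAI (-4.72 ± 0.50), AMD1 of polyamine synthesis (-4.56 ± 0.56) and the differentiation inhibitor ID1 (-4.48 ± 0.92) fell too. STAR, the cholesterol transporter of steroid-making cells, rose by 5.75 ± 0.47 (adjusted p = 0.00074, at least 14.7-fold) and MPC1L of pyruvate transport by 6.71 ± 1.06 (at least 23.4-fold). RFPL4AL1 rose by 5.13 ± 0.89, C1orf162 by 5.08 ± 0.72 and the fibrinogen gene FGA by 6.67 ± 1.81 (at least 34.8-fold), FGA on a probe with a run of 7 such bases and an SD of 5.46. With that probe passed over, chosen after the values were seen, VCX2 took its place at 5.01 ± 1.03.

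Cell cycle and oestrogen genes were also lower as sets in MCF7 with chloroform. Of 35 G2/M genes 33 were lower and 3 fell, 10 adjusted over the list alone, namely TTK (-2.19 ± 0.51), CENPE (-2.66 ± 0.66) and CDK1 (-1.99 ± 0.53) over all genes. Their median was -1.41 (adjusted p = 1.55e-07, and adjusted p = 0.624 with an estimated correlation). Without the 3 dimmest arrays, which left chloroform 2 alone, the median was -0.40. On chloroform 1 it was -2.33. Of 37 G1/S names 6 fell, 6 fell and 1 rose adjusted over the list alone, including the cyclin CCNE2 (-2.73 ± 0.51), GINS3 (-2.09 ± 0.39) and CDC25A (-3.24 ± 0.63). Their median was -0.57 (adjusted p = 0.000144, 0.0592 without chloroform 1, and adjusted p = 0.607 with an estimated correlation), and -0.13 without the 3 dimmest arrays. NRIP1, a corepressor of the oestrogen receptor (-4.05 ± 0.65), the insulin signalling adaptor IRS1 (-2.97 ± 0.49) and MYBL1 (-1.65 ± 0.43) fell, 3 of 29 oestrogen response genes in either count. Their median was -0.97 (adjusted p = 6.7e-05, and adjusted p = 0.442 with an estimated correlation), and -0.46 without the 3 dimmest arrays. Of 25 ribosome biogenesis genes 5 fell and 8 adjusted over the list alone, including POLR1B (-1.90 ± 0.37), POLR1A (-1.62 ± 0.38) and RRS1 (-1.68 ± 0.41). Their median was -0.77 (adjusted p = 0.000166, and adjusted p = 0.397 with an estimated correlation), and 1 fell and 1 rose without the 3 dimmest arrays. Of 27 hypoxia and glycolysis genes the lipid droplet gene HILPDA (-3.61 ± 0.86), VEGFA (-2.64 ± 0.69) and the glucose transporter SLC2A1 (-1.98 ± 0.49) fell and the glycolytic ALDOA (1.13 ± 0.31) rose, 3 and 1 also adjusted over the list alone. Their median was -0.60 (adjusted p = 0.0127, 0.0638 without chloroform 1, and adjusted p = 0.507 with an estimated correlation), and 5 fell and 0 rose without the 3 dimmest arrays, at a median of -0.27.

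The anti-apoptotic BCL2 (-3.13 ± 0.74) and XIAP (-2.08) fell, 2 of 12 anti-apoptotic genes and 3 adjusted over the list alone. Their median was -0.65 (adjusted p = 0.034, 0.0856 without control 1, 0.131 under quantile normalization, and adjusted p = 0.507 with an estimated correlation). Of 15 MCF7 line markers TRPS1 (-2.59) and GATA3 (-2.87) fell, 3 adjusted over the list alone. Their median was -0.97 (adjusted p = 0.0412, 0.197 without chloroform 1, 0.198 without the 3 dimmest arrays, 0.107 under quantile normalization, and adjusted p = 0.643 with an estimated correlation). WNT targets had MYC (-2.42 ± 0.67), DKK1 (-3.54) and RNF43 (-2.35) falling and TCF7 (2.07) rising, 3 and 2 adjusted over the list alone. Their median was -0.98 (adjusted p = 0.0443, 0.269 without chloroform 2, 0.0589 under quantile normalization, 0.143 with normexp, and adjusted p = 0.507 with an estimated correlation). In the integrated stress list VLDLR (-3.01) fell, 1 of 33 in either count. Their median was -0.53 (adjusted p = 0.0454, 0.964 without control 1, 0.124 under quantile normalization, and adjusted p = 0.815 with an estimated correlation). No fatty acid synthesis gene passed in either count. Their median was -0.49 (adjusted p = 0.028, 0.211 without chloroform 1, 0.124 without the 3 dimmest arrays, 0.167 under quantile normalization, and adjusted p = 0.643 with an estimated correlation). In all, 842 genes rose and 1108 fell, and 32.5% of the risers against 88.6% of the fallers were annotated as protein coding, while leukocyte markers had a median of 1.2 (adjusted p = 0.258). The limma count of 1950 was 135 without control 1, 812 without control 2, 233 without chloroform 1, 1061 without either HCT116 control array, 1098 without either HCT116 butanol array and 3655 without either HCT116 chloroform array. It was 711 with only the MCF7 arrays and 1 with only the groups compared. The median of all genes was 0.20 here and 0.05 with quantile normalization, and 3987 genes were higher and 3496 lower with normexp, against 511 and 1099 without the 3 dimmest arrays.

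In MCF7 with the ethanol fraction, oestrogen response and cell cycle genes were lower as sets, and 1421 genes fell and 757 rose. PDZK1, a scaffold protein induced by oestrogen, fell from 5.84 ± 0.06 to -0.08 ± 0.05 (-5.92 ± 0.55, adjusted p = 0.001, 60.4-fold). All 29 oestrogen response genes were lower and 20 fell, 28 adjusted over the list alone, with a median of -2.66 (camera adjusted p = 9.87e-19, and adjusted p = 0.136 with an estimated correlation). They included ESR1, the oestrogen receptor itself, which changed by -3.87 ± 0.90 (adjusted p = 0.025), the progesterone receptor PGR by -2.86 ± 0.74, MYBL1 by -3.64 ± 0.43 and IRS1 by -3.77 ± 0.49. Of 37 G1/S names 27 fell, 33 adjusted over the list alone, including E2F2 (-5.31 ± 0.55, adjusted p = 0.002), E2F1 (-3.06 ± 0.36) and MCM10 (-3.59 ± 0.42). Their median was -2.34 (adjusted p = 1.04e-21, and adjusted p = 0.251 with an estimated correlation). Of 35 G2/M genes 26 fell, 33 adjusted over the list alone, including the mitotic kinase CDK1 (-3.37 ± 0.53), the topoisomerase TOP2A (-4.51 ± 0.78) and TTK (-2.81 ± 0.51). Their median was -2.75 (adjusted p = 6.27e-19, and adjusted p = 0.442 with an estimated correlation). Without the 3 dimmest arrays, which left ethanol 2 alone, the G2/M median was -1.81. On ethanol 1 it was -3.71. Of 15 MCF7 line markers 9 fell, 13 adjusted over the list alone, including GREB1 (-3.53 ± 0.51), MGP (-3.98 ± 0.62) and, on a probe with a run of 7 alternating G and A bases, CA12 (-4.95 ± 0.93). Their median was -2.88 (adjusted p = 1.34e-07, and adjusted p = 0.316 with an estimated correlation), and 6 fell without the 3 dimmest arrays, at a median of -1.77. Of the 15 line markers 7, among them GREB1, CA12, PGR and ESR1, stand on the oestrogen list too.

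NRF2 targets and autophagy genes were higher in MCF7 with ethanol. HMOX1 went from 5.33 ± 0.31 to 9.54 ± 0.11 (4.21 ± 0.45, adjusted p = 0.002, 18.5-fold). FTL rose by 2.67 ± 0.32 and SRXN1, which repairs oxidised peroxiredoxins, by 3.08 ± 0.57. Of 26 NRF2 targets 9 rose, 10 adjusted over the list alone. Their median was 1.2 (adjusted p = 3.6e-06, and adjusted p = 0.17 with an estimated correlation). GABARAPL1 of the autophagosome rose by 3.84 ± 0.58 and SQSTM1 by 2.68 ± 0.55. Of the 28 listed, 6 autophagy and lysosome genes rose and 1 fell, 10 and 1 adjusted over the list alone. Their median was 0.70 (adjusted p = 0.000829, 0.175 with normexp, and adjusted p = 0.442 with an estimated correlation). The MAPK-responsive ETV5 rose by 4.44 ± 0.79, FOSL1 by 4.29 ± 1.06 and DUSP5 by 2.25 ± 0.50. Of 27 immediate early genes 5 rose, 8 adjusted over the list alone. Their median was 0.71 (adjusted p = 0.00533, 0.151 without control 2, 0.0939 with normexp, and adjusted p = 0.507 with an estimated correlation), and 1 rose without the 3 dimmest arrays. Of 25 ribosome biogenesis genes 9 fell, 14 adjusted over the list alone, including POLR1B (-2.23 ± 0.37), DKC1 (-1.70 ± 0.35) and BOP1 (-1.55 ± 0.33). Their median was -1.24 (adjusted p = 5.19e-09, and adjusted p = 0.14 with an estimated correlation), and 2 fell without the 3 dimmest arrays. The epithelial genes MUC1 (-4.06), KRT19 (-3.50), KRT8 (-1.86) and E-cadherin CDH1 (-1.88 ± 0.48) fell, 4 of 22 and 5 adjusted over the list alone. Their median was -0.67 (adjusted p = 0.00786, 0.347 without ethanol 1, 0.362 without the 3 dimmest arrays, and adjusted p = 0.608 with an estimated correlation), and without those arrays 2 fell. Of 33 oxidative phosphorylation genes SDHA (-1.35) fell and none did adjusted over the list alone. Their median was -0.56 (adjusted p = 0.0102, 0.347 without ethanol 1, 0.27 without the 3 dimmest arrays, 0.12 under quantile normalization, and adjusted p = 0.837 with an estimated correlation).

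The largest single rises in MCF7 with ethanol were MMP1, a collagenase (6.47 ± 1.16, adjusted p = 0.011, at least 49.2-fold), the trypsin inhibitor SPINK1 (6.17 ± 1.45, adjusted p = 0.026) and the gastrin receptor CCKBR (5.97 ± 1.18, at least 19.1-fold). The ribosomal RNA probe RNA18S5 rose by 5.64 ± 1.02, from -0.65 ± 0.03 to 4.99 ± 1.04, and the phospholipase PLA2G2F by 5.12 ± 1.40. Next to PDZK1, the largest falls were CDCA7 (-5.83 ± 0.88), a MYC and E2F target, the lipid transporter ABCA12 (-5.82 ± 0.94), the lysyl oxidase LOXL4 (-5.77 ± 0.66) and the potassium channel KCNJ8 (-5.69 ± 1.04, at least 12.2-fold lower). Of the risers 47.8% and of the fallers 83.3% were annotated as protein coding. The limma count of 2178 was 131 without control 1, 427 without control 2, 97 without ethanol 1, 3648 without ethanol 2, 1418 without either HCT116 control array and 1423 without either HCT116 butanol array. It was 219 with only the MCF7 arrays and 0 with only the groups compared. The split was 784 higher and 3050 lower with normexp and 569 and 690 without the 3 dimmest arrays, and the median of all genes was 0.18 with normexp against 0.09 here.

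**Figure D3:**
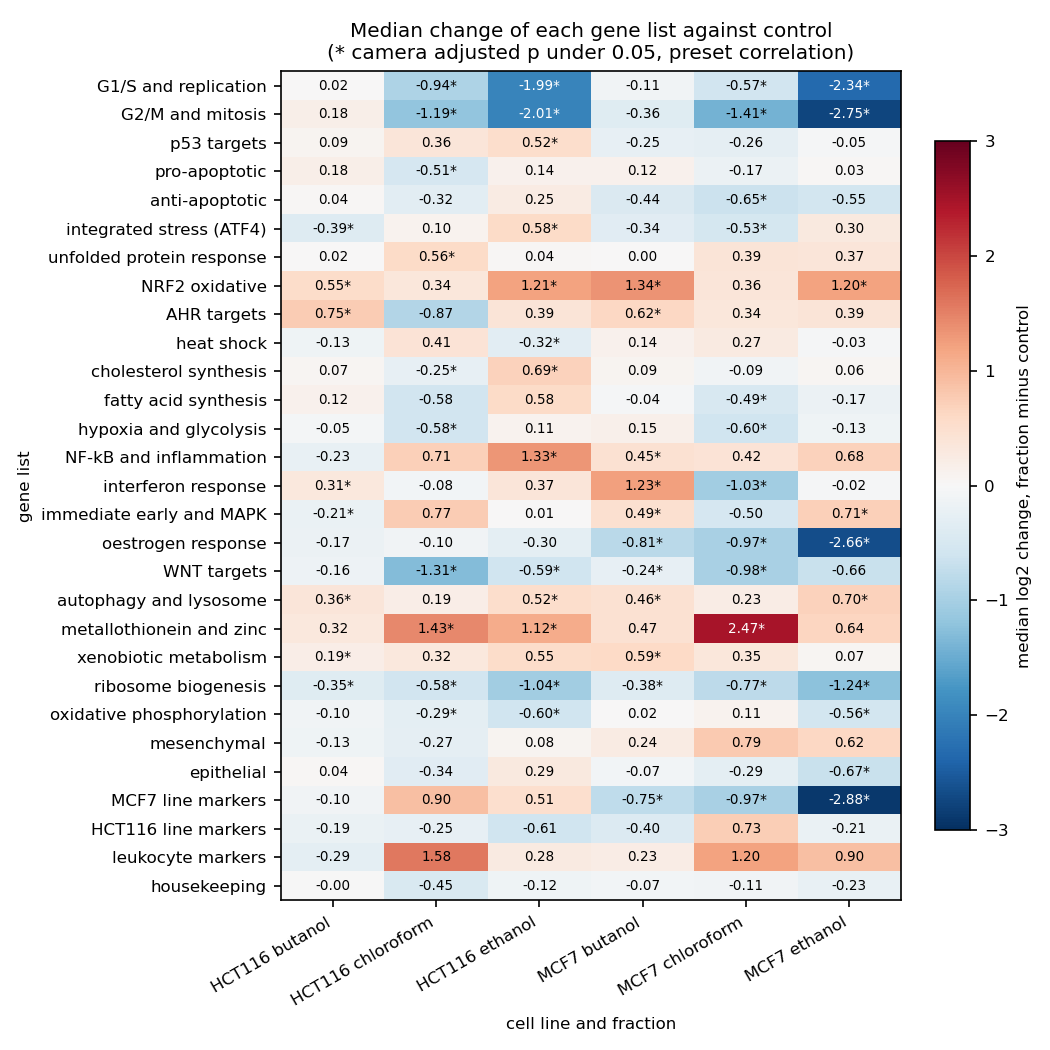
Median log2 change of the members of each of 29 gene lists (vertical axis) in the 6 comparisons with control (horizontal axis), with an asterisk where the camera adjusted p with its preset correlation is under 0.05. The G1/S row reads -1.99 and -2.34 with ethanol against 0.02 and -0.11 with butanol, and the oestrogen row -2.66 for MCF7 with ethanol.

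Lists that passed in no comparison with control were the mesenchymal list, with medians between -0.27 and 0.79 and adjusted p between 0.102 and 0.445, and the HCT116 line markers, between -0.61 and 0.73 (adjusted p 0.262 to 0.816). Leukocyte markers lay between -0.29 and 1.58 (adjusted p 0.174 to 0.647) and housekeeping genes between -0.45 and -0.00 (adjusted p 0.253 to 0.94). The highest leukocyte medians were with chloroform. Of 15 housekeeping genes, 2 passed in HCT116 with chloroform and 2 in MCF7 with ethanol. In the order butanol, chloroform and ethanol, 8, 10 and 13 lists passed in HCT116 and 11, 12 and 10 in MCF7. With 1 array left out, HCT116 butanol had 5 without butanol 1, MCF7 butanol 7 without butanol 2 and MCF7 chloroform 7 without control 1. In the other lists the comparisons without a call had adjusted p of 0.0548 or more, the lowest for hypoxia and glycolysis in MCF7 with butanol (median 0.15). No list call held with an estimated correlation.

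**Figure D4:**
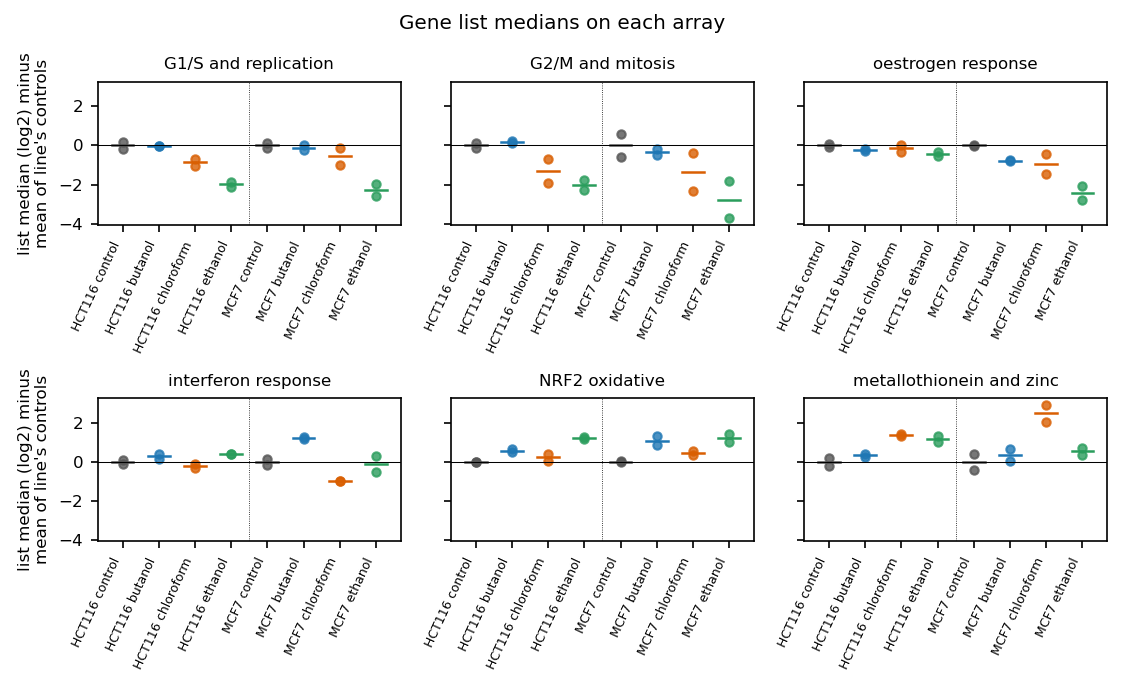
Median log2 level of 6 gene lists on each of the 16 arrays, minus the mean of the line's control arrays (points, one per array, bars at the mean of the pair). The ethanol arrays lie between -1.85 and -2.58 for G1/S genes, and the MCF7 interferon medians are 1.17 and 1.29 with butanol and -0.98 and -0.95 with chloroform.

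Fractions were compared with one another within HCT116. Against butanol, ethanol lowered MMP7 (-4.06 ± 0.45, adjusted p = 0.012, at least 3.76-fold lower), the peptide hormone gene CCK (-3.24 ± 0.50) and the axon guidance gene SEMA3A (-3.21 ± 0.46, at least 2.34-fold lower). It raised KRT34 (4.69 ± 0.51, adjusted p = 0.012, at least 14.4-fold), SLCO2B1 (4.35 ± 0.57, at least 15.8-fold) and ACRC (3.85 ± 0.49). The G1/S list was lower with ethanol than with butanol by a median of -2.03 (camera adjusted p = 6.16e-38, and adjusted p = 0.371 with an estimated correlation). It was lower than with chloroform by -1.08 (adjusted p = 5.64e-05, and adjusted p = 0.635 with an estimated correlation). Against chloroform, ethanol had higher DKK1 (4.40 ± 0.96, adjusted p = 0.025), C11orf86 (4.69 ± 0.54, at least 8.7-fold) and the endothelial junction gene HEG1 (4.23 ± 0.65), and higher cholesterol synthesis genes as a set. Their median was 1.40 (adjusted p = 6.24e-10, and adjusted p = 0.38 with an estimated correlation). IFNA22P (-7.20 ± 1.07, at least 55.5-fold lower), KIF25-AS1 (-6.32 ± 0.68, at least 16.2-fold lower) and C6orf222 (-5.79 ± 1.19) were lower with ethanol than with chloroform. Against butanol, chloroform lowered DKK1 (-5.55 ± 0.96, adjusted p = 0.0046), IER5L (-4.67 ± 0.64) and UBASH3B (-4.58 ± 0.36). Its 3 largest rises, LRRC2 (8.97 ± 1.96), GPR179 (8.43) and CD86 (8.33 ± 1.89), were on probes with runs of 11, 11 and 12 alternating G and A bases. Without such probes, chosen after the values were seen, they were C6orf222 (7.31 ± 1.19), TMEM30C (6.85 ± 1.48) and FAM71A (6.79 ± 1.03). The G2/M list was lower with chloroform than with butanol. Its median was -1.51 (adjusted p = 4.36e-09, and adjusted p = 0.638 with an estimated correlation).

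The limma counts higher and lower in HCT116 were 3338 and 1631 for chloroform against butanol, but 1533 and 1517 with quantile normalization. They were 26 and 13 for ethanol against butanol, but 111 and 507 with normexp and 454 and 485 without the 3 dimmest arrays. For ethanol against chloroform they were 592 and 1104, but 656 and 531 with quantile normalization and 650 and 382 with normexp. The count of 4969 for chloroform against butanol was 814 without butanol 2, 1471 without butanol 1, 1682 without chloroform 2 and 7457 without chloroform 1. The 39 for ethanol against butanol was 0 without ethanol 2, 1 without butanol 2, 15 without butanol 1, 151 without either chloroform array, 22 without any 1 control array, 20 without either MCF7 butanol array and 65 without either MCF7 ethanol array, and 0 with only the HCT116 arrays or with the block. The 1696 for ethanol against chloroform was 42 without ethanol 2, 99 without chloroform 2, 401 without ethanol 1, 6231 without chloroform 1, 1036 without either control array and 1070 without either butanol array. With only the groups compared all 3 counts were 0.

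In MCF7 the interferon list separated butanol from chloroform. OAS1, an antiviral enzyme, was lower with chloroform than with butanol by -6.41 ± 1.21 (adjusted p = 0.01) and IFIT1 by -4.67 ± 0.59 (adjusted p = 0.0023), with a list median of -2.40 (camera adjusted p = 3.28e-15, and adjusted p = 0.371 with an estimated correlation). The stem cell factor SOX2 was also lower (-5.33 ± 1.39), and STAR (5.42 ± 0.47, at least 17.8-fold), MPC1L (5.77 ± 1.06) and FGA (7.57 ± 1.81, at least 42-fold, run of 7) were higher. With such probes passed over, after the values were seen, ANKRD30A (5.40 ± 1.2) took the place of FGA. Ethanol against butanol lowered RRM2, which makes deoxynucleotides (-4.98 ± 0.97, adjusted p = 0.03), CDCA7 (-4.81 ± 0.88) and E2F8 (-4.69 ± 0.90). The lists of G1/S (median -2.40, adjusted p = 1.19e-26, and adjusted p = 0.371 with an estimated correlation) and oestrogen response genes (-1.75, adjusted p = 2.65e-12, and adjusted p = 0.371 with an estimated correlation) were lower. It raised REXO1L1P (4.78 ± 1.11, at least 9.03-fold), the imprinted RTL1 (4.63 ± 0.79, at least 5.33-fold) and ZNF577 (4.36 ± 0.49, adjusted p = 0.003). Ethanol against chloroform raised the stromelysin MMP10 (4.28 ± 0.95, at least 4.08-fold), GID4 (4.13 ± 0.64) and the lipid-sensing receptor PPARA (4.07 ± 0.94, at least 7.32-fold). It lowered LOXL4 (-5.37 ± 0.66, at least 8.72-fold lower), FOXI1 (-5.23 ± 0.88) and STAR (-4.48 ± 0.47, at least 8.61-fold lower). Between these 2 fractions G1/S (-1.80, adjusted p = 2.73e-13, and adjusted p = 0.38 with an estimated correlation) and metallothionein genes (-1.88, adjusted p = 7.62e-06, and adjusted p = 0.371 with an estimated correlation) were lower with ethanol. Interferon genes were higher (1.09, adjusted p = 1.59e-06, and adjusted p = 0.38 with an estimated correlation).

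The MCF7 counts higher and lower were 1650 and 1061 for chloroform against butanol, but 799 and 960 with quantile normalization and 943 and 1138 without the 3 dimmest arrays. They were 293 and 410 for ethanol against butanol, but 6131 and 4007 with normexp and 267 and 171 without the 3 dimmest arrays. For ethanol against chloroform in MCF7 they were 297 and 453, but 594 and 550 with quantile normalization and 512 and 427 without the 3 dimmest arrays. The 2711 for chloroform against butanol was 397 without chloroform 1, 465 without butanol 1, 489 without butanol 2, and 1728, 1776 and 4903 without either HCT116 control, butanol or chloroform array. The 703 for ethanol against butanol was 9 without butanol 1, 36 without butanol 2, 13 without ethanol 1, 2675 without ethanol 2, 392 without either control array and 1321 without either chloroform array. Without either HCT116 control, butanol, chloroform or ethanol array it was 176, 208, 1539 and 290. The 750 for ethanol against chloroform was 91 without chloroform 2, 175 without ethanol 1 and 1366 without ethanol 2, and 394, 372, 1912 and 446 without either HCT116 control, butanol, chloroform or ethanol array.

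Changes were correlated across genes, those with shared controls beside 100 simulations without effects. Chloroform and ethanol gave r = 0.571 in HCT116 and 0.66 in MCF7, with covariances of 0.704 and 0.927. Butanol gave r of 0.173 with chloroform and 0.432 with ethanol in HCT116, and 0.16 and 0.388 in MCF7. Its covariances were 0.118 and 0.189, and 0.121 and 0.3. Simulated r was near 0.5 and covariance near 0.168 for every pair, although group spreads differed, so r had no benchmark. In HCT116 that covariance may be too high, as controls had 0.643 times the pooled spread. Between the lines, whose controls are separate, r was 0.158 for butanol, 0.607 for chloroform and 0.445 for ethanol, and 435 genes rose and 424 fell with chloroform in both lines, with 29 in opposite directions.

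The interactions asked whether the lines responded differently. Chloroform changed 163 genes differently: CHST2, a sulfotransferase, by -2.62 in HCT116 and 3.68 in MCF7 (difference 6.30 ± 0.85, adjusted p = 0.011), and PDE4B by -4.63 and 1.19 (5.81 ± 0.69, adjusted p = 0.0075). Ethanol changed 33 genes differently, including PDZK1, by 3.60 in HCT116 and -5.92 in MCF7 (difference -9.52 ± 0.77, adjusted p = 0.00071), and MMP7, by -5.72 and 0.77 (6.5 ± 0.64, adjusted p = 0.0031). Oestrogen response genes changed with ethanol by a lower median in MCF7 than in HCT116 (difference -2.28, camera adjusted p = 2.49e-16, and adjusted p = 0.28 with an estimated correlation). For butanol the limma test found 0 genes that differed, with 680 at an unadjusted p under 0.05. The butanol count was 4 without HCT116 butanol 1. The count of 163 was 15 without HCT116 control 1, 18 without HCT116 control 2 or MCF7 control 1, 52 without MCF7 control 2, 417 without HCT116 chloroform 2, 518 without HCT116 chloroform 1, 69 without either HCT116 ethanol array and 73 without either MCF7 butanol array. The count of 33 was 2 without any 1 control array, 3 without HCT116 ethanol 2, 4 without MCF7 ethanol 1 or either HCT116 butanol array, 7 without either MCF7 butanol array, 137 without either HCT116 chloroform array and 402 without MCF7 ethanol 2.

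The control arrays were compared as a check of the line labels. ESR1 was higher in MCF7, at 5.15 ± 0.41 against -3.86 ± 0.21 (9.01 ± 0.90, adjusted p = 1.3e-05, 516-fold). Also higher were the secreted trefoil peptides TFF1 (9.03 ± 0.49, adjusted p = 1.1e-07, 522-fold) and TFF3 (10.20 ± 0.71, at least 1030-fold) and the luminal transcription factor GATA3 (7.66 ± 0.78). Of the 15 MCF7 line markers 14 were higher in MCF7, and ANKRD30A did not pass (2.69 ± 1.2, adjusted p = 0.11). The intestinal transcription factor CDX2 was lower in MCF7, at -5.73 ± 0.34 against 3.57 ± 0.16 (-9.30 ± 0.52, adjusted p = 1.4e-07, at least 150-fold lower). Also lower were CDKN2A, which MCF7 is known to lack (-6.22 ± 0.40, 74.7-fold), the adhesion receptor CD44 (-4.62 ± 0.40) and MSLN (-4.64 ± 0.51, at least 15.3-fold lower). VIM (-1.53 ± 0.52) was lower as well, and GPA33 (-2.25 ± 0.63) too, but with normexp it was 0.035 (adjusted p = 0.888), while ASCL2 (10.17 ± 0.77, at least 241-fold) and VIL1 (2.41 ± 0.80) of the HCT116 list were higher in MCF7, and EPHB2, LCK and TDGF1 did not pass. With limma 4887 genes were higher and 3253 lower in MCF7 (3470 and 3489 with quantile normalization), and the count of 8140 was 4760 without HCT116 control 2, 5273 without HCT116 control 1 and 5159 without MCF7 control 1. Line and slide coincide, so a difference between slides is part of this comparison.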

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

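The tests of gene and list differences between the lines were set before the data were examined, and all tests of explanations in this part were chosen only after the result was seen.

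Results that differed between the lines, by an interaction test in limma, were 163 genes with chloroform. HOXB8 changed by -4.16 in HCT116 and 2.42 in MCF7, a difference of 6.58 (adjusted p = 0.038), CHST2 differed by 6.30 (adjusted p = 0.011) and PDE4B by 5.81 (adjusted p = 0.0075). C9orf152 differed by -7.22 (adjusted p = 0.017), CDH18 by -6.34 (adjusted p = 0.0083), and EGR3, whose probe has a run of 7 alternating G and A bases, by -7.08 (adjusted p = 0.036, and 0.074 without the 3 dimmest arrays). With ethanol 33 genes differed. MMP7 differed by 6.5 (adjusted p = 0.0031), CCK by 5.95 (adjusted p = 0.013) and RGCC by 5.12 (adjusted p = 0.026). PDZK1 differed by -9.52 (adjusted p = 0.00071), CDYL2 by -5.17 (adjusted p = 0.026) and SPANXA1 by -7.90 (adjusted p = 0.048, and 0.078 without the 3 dimmest arrays). The 163 became 15 without HCT116 control 1 and 518 without HCT116 chloroform 1, and the 33 became 2 without any 1 control array and 402 without MCF7 ethanol 2.

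Gene lists also differed between the lines by camera with its preset correlation (adjusted p up to 0.0465). None held with an estimated correlation (lowest adjusted p = 0.28). Differences are medians of the effect in MCF7 minus that in HCT116. With butanol they were 0.946 for interferon response (adjusted p = 4.54e-07), 0.589 for NF-kB, 0.54 for immediate early, 0.467 for mesenchymal, 0.251 for NRF2, -0.39 for oestrogen response and -0.763 for MCF7 line genes. With chloroform they were -1.17 for interferon response, -1.12 for MCF7 line genes, -0.98 for p53 targets, -0.669 for integrated stress, 0.413 for oxidative phosphorylation, 0.621 for metallothionein, 0.919 for mesenchymal, 0.944 for WNT targets and 1.06 for HCT116 line genes. With ethanol they were -3.07 for MCF7 line genes, -2.28 for oestrogen response (adjusted p = 2.49e-16), -1.2 for epithelial, -0.838 for fatty acid synthesis, -0.802 for G2/M, -0.469 for p53 targets, 0.468 for mesenchymal and 0.858 for immediate early genes. Most MCF7 line genes, some on the oestrogen list, were lower in HCT116 controls. Less room to fall there was not told apart from a different response. Without the 3 dimmest arrays, differences no longer passed for ethanol G2/M, fatty acid synthesis and epithelial genes. Nor did they for chloroform MCF7 line, HCT116 line, metallothionein, WNT and mesenchymal genes. Others passed only then: for chloroform G2/M, G1/S, unfolded protein, NF-kB and immediate early genes, for butanol G2/M and for ethanol oxidative phosphorylation. Outside the measured genes, the negative control spots of HCT116 chloroform 2 read 31.7, against 19.6 to 22.1 on the other arrays.

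The rises with chloroform in HCT116 were weighed first. Runs of alternating G and A bases may set the signal of probes with runs of 9 or more: these rose by a median of 4.92 in 45 genes whose other probes rose by 0.97, beside 1.04 for all probes, while the 658 probes with runs of 7 or 8 rose by 1.48, so little above all probes that the run cannot be the whole cause there. A first version of this test, with all runs of 7 or more and no comparison with all probes, pointed the other way: the other probes of 247 genes rose by 1.38, over 1 in 163. Scaling may lift dim genes, since the median unscaled signal of the dimmest genes, by quartile of mean level, differed by 0.07 between the chloroform arrays while their 75th percentiles differed by -0.79; a first version compared the median change of those genes, 1.11, with 0 under quantile normalization, which removes such a shift by construction. Of the 3257 rises 94 were on run probes, so these cover a small part, and scaling was not separated from an effect of the fraction for the rest, which stays open.

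The fall of the cell cycle lists with ethanol was weighed next. Of 10000 random lists matched on mean level, 0 had a median as low in HCT116 and 0 in MCF7, where the lowest were -0.67 and -1.05. Quantile normalization took the median of the dimmest genes from 0.22 to -0.07 and from 0.39 to 0.04, and left G2/M at -1.95 (adjusted p = 2.02e-17) and -2.69 (adjusted p = 3.24e-17, preset correlation). Both argue against a shift set by expression level as the whole cause. Low signal of the arrays was tested against the chloroform arrays, where the log2 75th percentile with ethanol minus that with chloroform was 0.33 in HCT116 and -0.12 in MCF7: G1/S genes were lower with ethanol by medians of -1.08 and -1.80 with no overlap of arrays, which argues against it for that list. For G2/M genes the differences were -0.572 (adjusted p = 0.391) and -1.40 (adjusted p = 5.29e-07) but single arrays overlapped, HCT116 chloroform 1 at -1.92 beside ethanol 2 at -1.74, and MCF7 chloroform 1 at -2.33 beside ethanol 2 at -1.81. Low signal that acts other than by level and an effect of ethanol cannot be told apart there. A first version, which compared G1/S alone and required brighter ethanol arrays, left MCF7 undecided and was replaced, and an effect of ethanol on the G1/S genes stays a hypothesis, which may hold for these arrays alone.

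The interferon list in MCF7, higher with butanol and lower with chloroform, was weighed last. One deviating control array was tested by leaving out each: the butanol median stayed at 0.99 or above and the chloroform median at -0.99 or below, which argues against it. Of 10000 matched random lists, 0 were as extreme with either fraction, though with chloroform the lowest random median was -1.01 beside -1.03, which argues against a shift set by level. A response that differs between the lines stays open, since the difference of 0.946 passed with the preset correlation and had adjusted p = 0.407 with an estimated correlation. Slide and line coincide, and a difference between fractions in how cells were grown or handled was not tested, so an effect of the fractions may be only 1 of the open explanations.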

How the results depend on the processing

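The settings without the 3 dimmest arrays, with only the groups compared and without probes of long G and A runs were chosen only after the results were seen. Counts are genes that passed, in the order HCT116 butanol, chloroform and ethanol, then MCF7, unless named. Leaving out such probes left each of the 22 counts of genes and lists within 1.5 times its value, and a 2-fold minimum did so for each of the 16 gene counts. With every probe apart, only the ethanol difference between lines moved, to 66. The cause was not tested except where the setting itself names it.

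With quantile normalization HCT116 butanol gave 0, HCT116 chloroform 2741 and MCF7 butanol 10. Chloroform against butanol gave 3050 in HCT116 and 1759 in MCF7, and in MCF7 ethanol gave 418 against butanol and 1144 against chloroform. The differences between lines were 2 for butanol and 53 for ethanol, and 7 lists passed for MCF7 chloroform. With normexp the comparisons with control gave 3, 12092, 1987, 9, 7483 and 3834. Chloroform against butanol, ethanol against butanol and ethanol against chloroform gave 9492, 618 and 1032 in HCT116 and 14031, 10138 and 230 in MCF7, and the differences between lines were 708 for chloroform and 291 for ethanol. GPA33, lower in MCF7 controls, was 0.035 with normexp, a reversed sign. With the authors' table HCT116 butanol gave 7, MCF7 chloroform 1179, MCF7 chloroform and ethanol against butanol 1797 and 466, the butanol difference 2, and 4 lists passed for HCT116 butanol.

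With no filter on dim genes, which adds genes to the adjustment, HCT116 butanol gave 0 and ethanol 88, and MCF7 4, 880 and 909. HCT116 ethanol gave 9 against butanol and 717 against chloroform, the MCF7 pairs 1798, 77 and 216, and the differences 27 for chloroform and 4 for ethanol. With genes above background on all arrays, fewer genes were tested: HCT116 butanol gave 0, chloroform 2853, MCF7 butanol 1, HCT116 chloroform against butanol 2881, ethanol against butanol 113, the differences 2 for chloroform and 5 for ethanol, and the control lines 4263. Lists that passed were 6 for MCF7 butanol and 7 for MCF7 chloroform.

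With only the arrays of HCT116, fewer arrays set the spread, and butanol gave 0, ethanol 43 and ethanol against butanol 0. With only those of MCF7 the comparisons with control gave 6, 711 and 219 and the pairs 1342, 24 and 0. With only the groups compared the comparisons with control gave 0, 144, 1390, 10, 1 and 0, the pairs 0, 0 and 0 in HCT116 and 1268, 0 and 0 in MCF7, and the differences 0 for chloroform and 60 for ethanol. The block for the HCT116 titles gave 0 for butanol, 0 for ethanol, 0 for ethanol against butanol and 953 for ethanol against chloroform, and the numbers paired the arrays weakly: r was 0.15 to 0.2 between control, butanol and ethanol, and -0.028 to 0.03 with chloroform. Without the 3 dimmest arrays HCT116 butanol gave 0 and ethanol 1938, MCF7 butanol 71 and ethanol 1259, HCT116 ethanol 939 against butanol and 826 against chloroform, MCF7 ethanol against butanol 438, and the differences 1037 for chloroform and 142 for ethanol. With an estimated correlation in camera 0 lists passed in each of the 6 comparisons with control.

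Leaving out 1 array at a time leaves a group with 1 array, assumed to vary like the others. The lowest and highest counts were 0 and 23 for HCT116 butanol, 800 and 7220 for chloroform, 3 and 795 for ethanol, and 0 and 26, 135 and 3655, and 97 and 3648 for MCF7. For the pairs they were 814 and 7457, 0 and 151, and 42 and 6231 in HCT116, and 397 and 4903, 9 and 2675, and 91 and 1912 in MCF7. For the differences between lines they were 0 and 4, 15 and 518, and 2 and 402, and for the control lines 4760 and 9289. Lists that passed ran from 5 to 9, 7 to 12 and 11 to 14 in HCT116, and from 7 to 13, 7 to 14 and 10 to 14 in MCF7. For named genes, 460 calls stayed and 391 were lost when an array was left out.

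Named genes kept their call in 173 cases and lost it in 27 with quantile normalization, 173 and 25 with normexp, 181 and 18 with the authors' table, 158 and 42 with no filter, and 188 and 1 without run probes. The counts were 183 and 16 without the 3 dimmest arrays, 66 and 133 with only the groups compared, 48 and 28 with only the HCT116 arrays, 41 and 44 with only the MCF7 arrays, and 42 and 34 with the block. Signal over background limits the dim arrays: genes at the floor have bounds, not folds, and the 75th percentile was 46.8 on the dimmest.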

Other observations

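The gene families here were chosen only after the values were seen, and their list tests share 1 adjustment over 48 tests, 8 families in 6 comparisons. Zinc finger genes were lower in MCF7 with chloroform: 74 of 463 fell and 7 rose, with a median of -0.76 (camera adjusted p = 4.99e-11, and adjusted p = 0.972 with an estimated correlation). The median was -0.76 with quantile normalization, -0.23 with normexp and -0.87 without the 3 dimmest arrays. In HCT116 with chloroform 46 rose and 30 fell, and the median had no stable sign: -0.07, -0.23 with quantile normalization and 0.36 without the 3 dimmest arrays.

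Histone genes were higher in HCT116 with chloroform: 33 of 63 rose, with a median of 1.85 (camera adjusted p = 2.22e-10, and adjusted p = 0.972 with an estimated correlation), 1.7 with quantile normalization, 0.89 with normexp and 1.06 without the 3 dimmest arrays. Small nucleolar RNA genes rose in 39 of 202 in HCT116 with chloroform (median 1.11, and 0.8 with quantile normalization). In MCF7 32 rose with chloroform and 13 with ethanol, where the median of 0.84 was 0.21 without the 3 dimmest arrays. In HCT116 with chloroform 96 of 102 olfactory receptor genes were higher and 26 rose, with a median of 1.22 (adjusted p = 1.43e-07, and adjusted p = 0.972 with an estimated correlation) that was 0.34 with quantile normalization. Of 79 ribosomal protein genes 76 were higher, with a median of 0.81 (adjusted p = 1.58e-05, and adjusted p = 0.972 with an estimated correlation) that was 0.01 with quantile normalization.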
